A study of Caenorhabditis elegans with 6 samples.

How the data were processed

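The data were RNA-seq read counts from 6 libraries of male C. elegans, 3 wild type and 3 csr-1a mutant, each made from 5000 cells sorted as rectal valve and rectal gland cells. The purity of the sort is not given in the sources used here. Per the labels' protocols, total RNA was taken from sorted cells in TRIzol and the libraries were made with the VAHTS Universal V8 RNA-seq kit. The authors deposited a single table of raw read counts per gene. Per the submitters' processing notes, fastp 0.20.1, STAR, featureCounts, Subread 2.0.0 and DESeq2 were used, without a stated order or role. The genome build, the annotation release and whether reads were counted by strand are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart, and near-identical genes may have shared or lost reads.

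The table held 46932 genes under WormBase identifiers, of which 46919 were found in the WBcel235 annotation (Ensembl release 115). Gene symbols and coordinates (1-based) came from that annotation by identifier, and 23431 genes had no count in any library. The build of the authors' own counting is not given, so coordinates describe the gene in WBcel235 and not the counted intervals. All 6 count columns were matched to samples by name. Groups came from the genotype in the sample labels. No pair of libraries within a group agreed within sampling noise, since the chi-square per degree of freedom was at least 8.66, so every library counted as a replicate. That excess does not show that the libraries came from separate cultures, which the labels do not state. Ribosomal RNA took 74.4% to 78.4% of the counts and was kept in the library totals, so that a CPM value is relative to a total mostly of ribosomal RNA. The counts left for other genes, 4542195 to 11541671 per library, set the precision of gene levels.

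Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with edgeR's filterByExpr by group (minimum count 10, minimum total count 15), scaled by the trimmed mean of M values, and tested with the quasi-likelihood test (glmQLFit with robust=TRUE, glmQLFTest) on the group alone, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The biological coefficient of variation was 0.465. CPM values used the same scaling. The procedure was tested on simulated counts drawn from the means and totals of these libraries. There 26 of 100 genes changed 2-fold and 89 of 100 changed 4-fold were recovered. The changed genes were drawn only from genes above a minimum mean count, so these shares do not cover genes with few counts. Called too were 4 of 10965 unchanged genes, among 11195 tested.

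The design, the alternatives and 34 gene lists (pathways, families and markers of tissues that a sort of rectal cells could hold) were fixed before the data were examined. Of the list members given by name, 14 matched no gene. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the lists with at least 5 tested members. The same test with an estimated correlation, and fry, which asks whether a set's genes move on balance in a common direction without comparing the set with other genes, were run beside it. Members called were counted over all genes tested and also adjusted over the list alone. Chromosomal place was tested with two-sided Fisher's exact tests of called against other tested genes, with arms as the outer parts of autosomes cut into 3 equal lengths, and adjusted over 4 tests. A list's share of counts was taken over all counts outside ribosomal RNA.

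The text names csr-1, pnc-1, pcs-1 and him-8 whatever their result. It names the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups. It also names up to 3 members of each list with the smallest adjusted p under the threshold or, for a list passing camera with no such member, the member with the smallest p. This gave 68 genes. A gene named outside this rule is said to have been named after its values were seen. Not marked so are genes named as the most abundant (rrn-3.1 and dig-1), as the ends of a range (pax-3 and ajm-1) or as overlapping or near-identical genes.

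The alternatives were a replicate block, size factors of the DESeq2 kind, library totals alone, no low-count filter, a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, glmQLFit with robust=FALSE, an added threshold of 1 on the absolute log2 fold change, the 50 most abundant genes left out of library totals, sperm and germline genes left out, arms as the outer parts of autosomes cut into 4 and each library left out in turn. Chosen after seeing the data were leaving out ribosomal RNA genes, leaving out both libraries with the fewest genes detected and leaving out muscle list genes. The 6 libraries were also split into 3 and 3 in all 10 ways. GC content was not tested, because no genome sequence was used here.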

Results

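RNA was measured in cells sorted by fluorescence from young adult males of the nematode Caenorhabditis elegans, which the labels name as cells of the rectal valve and rectal gland at the end of the gut. The purity of the sort is not given in the sources used here. The sort used the red protein wrmScarlet driven by the promoters of pnc-1 and pcs-1 from extrachromosomal arrays, in a him-8 background. Loss of him-8, a zinc-finger protein that pairs the X chromosomes in meiosis, raises the share of males among the progeny. The parents of both groups had been heat-stressed at the late L4 larval stage. The wild-type group (3 libraries) carried a tagged csr-1a, and the mutant group (3 libraries) carried a csr-1a deletion; csr-1 encodes an Argonaute protein, which binds small RNAs. Each library was made from 5000 sorted cells, and the labels call the libraries of a group biological replicates without saying whether they came from separate cultures. The p-values therefore measure the spread between these libraries. The comparison addresses how loss of csr-1a changes the male tail, as stated in the series' design text.

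Total counts per library were 26577422, 18986348 and 17748698 in wild-type replicates 1, 2 and 3, and 47890863, 22470932 and 22778030 in mutant replicates 1, 2 and 3. Ribosomal RNA took 74.4% to 78.4% of these counts, most of them on the gene rrn-3.1, which left 4542195 to 11541671 counts per library for all other genes. The number of genes with a count was 19083, 18071 and 14012 in the wild-type libraries and 18101, 12757 and 18455 in the mutant libraries, so wild-type replicate 3 and mutant replicate 2 held the fewest. Outside ribosomal RNA the most abundant gene in all 6 libraries was dig-1, which encodes a giant extracellular matrix protein, at 16.17% ± 0.738 (SD, n = 3) of the remaining counts in wild type and 8.23% ± 1.45 (SD, n = 3) in the mutant (log2 fold change -1.13 ± 0.15, adjusted p = 0.00111). Levels below are normalised counts (CPM) after scaling, as mean ± SD of 3 libraries per group, log2 fold changes are mutant over wild type with their standard error, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

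The mutated gene itself, csr-1 (WBGene00017641, WBcel235 chromosome IV, 7957267 to 7962157, plus strand), was counted at 185, 209.5 and 267 CPM in the wild-type libraries and at 185, 157 and 153 CPM in the mutant libraries. Its log2 fold change of -0.42 ± 0.17 did not pass the test (adjusted p = 0.213). Counts were made per gene, so they do not separate the a isoform from the others, the extent of the deletion is not given in the sources used here, and 438 bp of the gene overlap frpr-10. The value is therefore no check of the genotype. The genes pnc-1 and pcs-1, whose promoters drove the wrmScarlet reporter used for the sort, were both higher in the mutant. The nicotinamidase gene pnc-1 (WBGene00021395, chromosome IV, 184484 to 192151) went from 7.18 ± 2.2 to 22.9 ± 6.42 CPM, a log2 fold change of 1.68 ± 0.30 (adjusted p = 0.00618). The phytochelatin synthase gene pcs-1 (WBGene00003960, chromosome II, 11574941 to 11577740) went from 13.4 ± 3.14 to 30.3 ± 10.5 CPM, a log2 fold change of 1.19 ± 0.27 (adjusted p = 0.0259). By mean wild-type level outside ribosomal RNA they ranked 3803 and 2370. The 12 tested rectal markers and reporters lay between 0.41 CPM (pax-3) and 33.3 CPM (ajm-1, also found in other epithelia) in wild type. The coelomocyte genes cubn-1 and cup-4, chosen after their values were seen, stood at 1827 and 982 CPM. The call of pcs-1 ended without wild-type replicate 1, wild-type replicate 2 or mutant replicate 1 (adjusted p = 0.0964, 0.0759 and 0.0691), and that of pnc-1 ended when the libraries with the fewest genes were both left out (adjusted p = 0.0738). The level of him-8 was 1.54 ± 0.388 CPM in wild type and 1.36 ± 0.433 CPM in the mutant (log2 fold change -0.18 ± 0.61, adjusted p = 0.943).

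Of 11968 genes tested, 669 changed, 484 of them higher and 185 lower in the mutant. The median fold of the called genes was 5.83 among those higher and 1.87 among those lower, and 459 of the higher but 65 of the lower genes changed by at least 2-fold. Protein-coding genes made up 657 of the 669. At an unadjusted p under 0.05 stood 2018 genes, and in 24.8% of tested genes the 3 libraries of each group did not overlap, where chance gives 10%. Scaling by library totals alone gave 573 higher and 89 lower genes, so that 86.6% of the called genes were higher against 72.3% with the main scaling. The count of changed genes was 416 without wild-type replicate 1 and 422 without wild-type replicate 3, and the count of lower genes was 39 without wild-type replicate 1, 47 without wild-type replicate 3 and 101 without mutant replicate 3. With both libraries of fewest genes left out, an alternative chosen after seeing the data, 473 genes were higher and 56 lower.

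Of the 34 gene lists, body wall muscle had the highest median change. Of 33 tested members of the muscle list, 29 were higher and 0 lower in the mutant (30 higher and 0 lower when adjusted over the list alone), with a median log2 fold change of 3.82. The muscle myosin heavy chain gene unc-54 (WBGene00006789, chromosome I, 14855901 to 14863482) went from 249 ± 28.9 to 4064 ± 2120 CPM, a log2 fold change of 4.03 ± 0.32 (adjusted p = 9.39e-05). The troponin I gene unc-27 (WBGene00006764, chromosome X, 8789456 to 8790621) went from 19.3 ± 1.80 to 327 ± 166 CPM, and the myosin light chain gene mlc-2 (WBGene00003370, chromosome X, 17455792 to 17456586) from 24.1 ± 4.25 to 410.1 ± 185 CPM, although mlc-2 has a near-identical copy, mlc-1, with which reads can be shared. The 4 members that did not pass, named after their values were seen, were sgcb-1, unc-38, unc-45 and unc-112, with log2 fold changes of 2.77 ± 1.12, 1.96 ± 0.97, 0.34 ± 0.24 and 0.60 ± 0.29. Together the list members took 0.535% ± 0.0361 (SD, n = 3) of the counts outside ribosomal RNA in wild type and 6.99% ± 3.17 (SD, n = 3) in the mutant, with 10.6%, 4.97% and 5.37% in mutant replicates 1, 2 and 3. The list passed the camera test with a preset correlation between genes (adjusted p = 4.18e-106). It did not pass with an estimated correlation (adjusted p = 0.279 with an estimated correlation), and fry gave an adjusted p of 0.0343. None of the single libraries, when left out, ended the calls of unc-54, unc-27 or mlc-2.

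**Figure D1:**
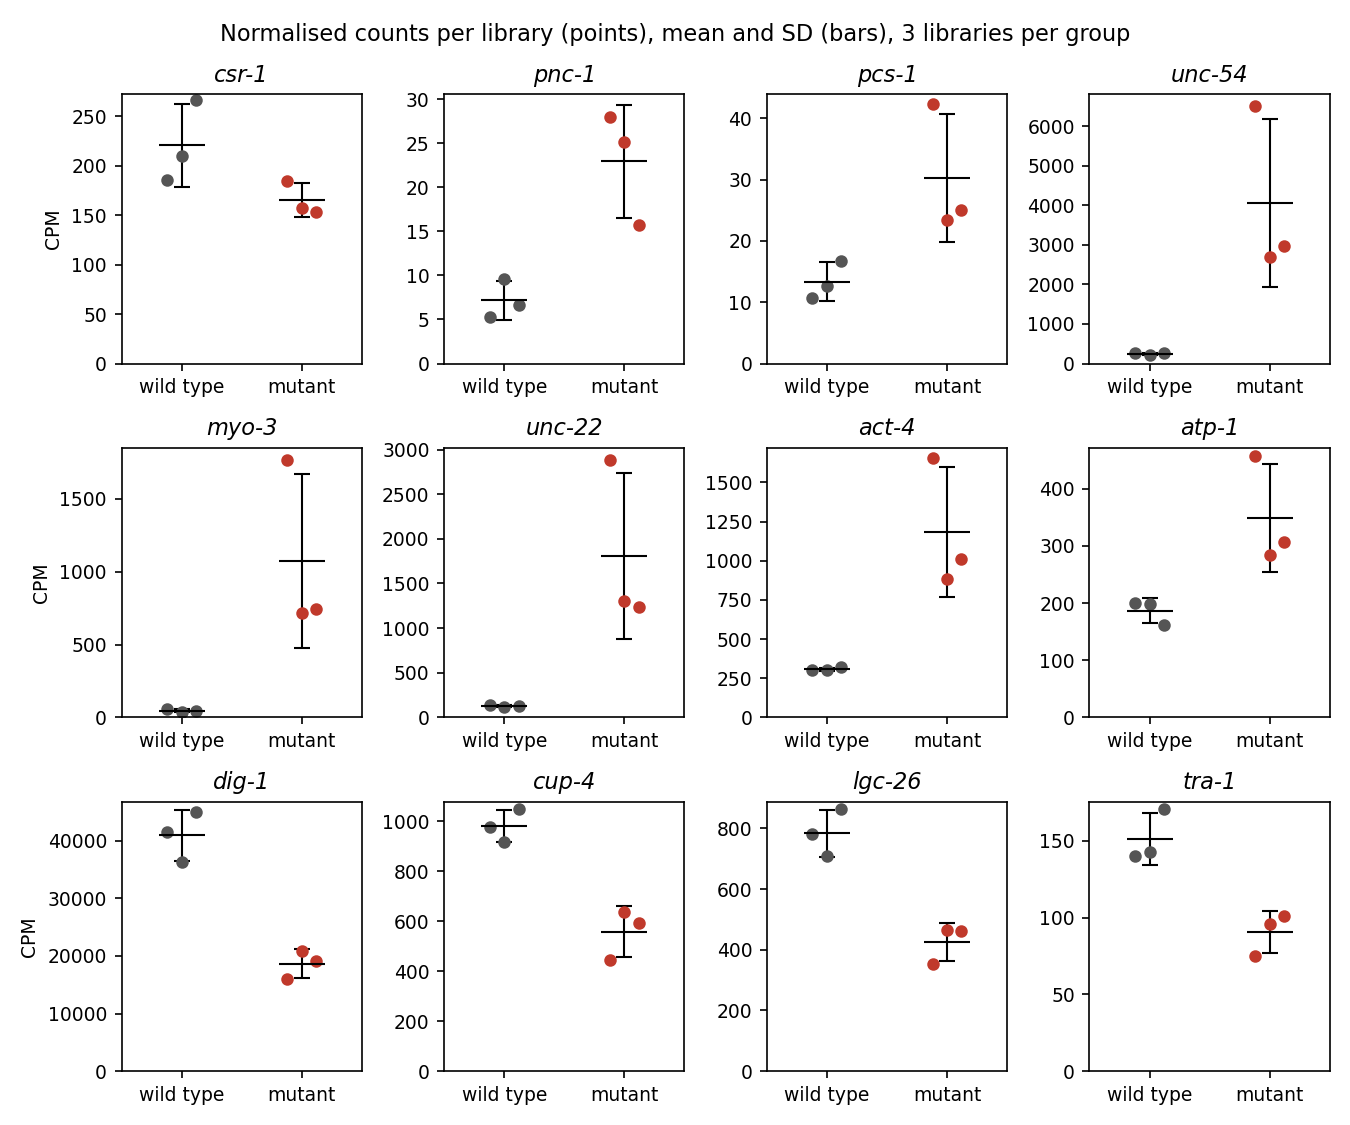
Normalised counts (CPM, linear axis from 0) of 12 genes in the 3 wild-type (grey) and 3 mutant (red) libraries, 1 point per library, with the group mean and SD as bars. The muscle gene unc-54 stands at 249 ± 28.9 CPM in wild type and 4064 ± 2120 CPM in the mutant, the coelomocyte gene cup-4 at 982 ± 64.8 and 558 ± 101 CPM, and csr-1 did not pass the test.

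The 10 largest rises under the naming rule were T21B6.3, B0310.1, F20D6.10, W06A7.2, C03H5.5, F35A5.1, unc-29, F54B11.9, tmc-2 and T23E7.2, with log2 fold changes of 5.20 ± 0.40, 5.13 ± 0.44, 4.90 ± 0.75, 4.88 ± 0.57, 4.87 ± 0.83, 4.84 ± 0.38, 4.76 ± 0.83, 4.72 ± 0.79, 4.70 ± 0.50 and 4.68 ± 0.35. Among them unc-29 encodes a subunit of the acetylcholine receptor of muscle and belongs to the muscle list. The most abundant was T21B6.3 (chromosome X, 10945160 to 10948952), which went from 11.2 ± 2.93 to 414 ± 242 CPM. W06A7.2, F20D6.10, F54B11.9, C03H5.5 and unc-29, each below 0.3 CPM on average in wild type, were not called by limma-voom (adjusted p = 0.154, 0.16, 0.136, 0.337 and 0.105). In the same libraries the muscle list took 6.99% of the counts outside ribosomal RNA in the mutant, against 0.535% in wild type.

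The 10 largest falls were smaller. They were C10E2.1, the pseudogene WBGene00013841, ins-24, Y39A1A.16, F45D3.4, phy-2, nhr-133, C39D10.2, ZC21.6 and pgp-9, with log2 fold changes of -2.61 ± 0.68, -2.0 ± 0.31, -1.94 ± 0.48, -1.93 ± 0.45, -1.80 ± 0.44, -1.78 ± 0.24, -1.75 ± 0.37, -1.75 ± 0.42, -1.73 ± 0.28 and -1.73 ± 0.23. The collagen prolyl 4-hydroxylase gene phy-2 (WBGene00004025, chromosome IV, 12211097 to 12215987) went from 49.97 ± 15.2 to 14.6 ± 2.2 CPM (adjusted p = 0.00111). The gene pgp-9 (WBGene00004003, chromosome V, 17755892 to 17764751), which encodes an ATP-driven membrane transporter, went from 138 ± 39.8 to 41.8 ± 7.90 CPM (adjusted p = 0.00111). The calls of phy-2, pgp-9, ZC21.6 and WBGene00013841 held in every alternative run, and those of the other 6 ended without wild-type replicate 1, without wild-type replicate 3 and without other single libraries. The highest adjusted p without a single library was 0.168 for C10E2.1, 0.19 for ins-24, 0.146 for Y39A1A.16, 0.169 for F45D3.4 and 0.158 for C39D10.2, each without wild-type replicate 3, and 0.147 for nhr-133 without wild-type replicate 1. C10E2.1 was also not called by DESeq2 (adjusted p = 0.105) or without a low-count filter (adjusted p = 0.0649). A pseudogene can share reads with its parent gene, so the value of WBGene00013841 is uncertain. Beside these falls, the excretory and coelomocyte list took 1.03% of the counts outside ribosomal RNA in wild type and 0.675% in the mutant, and the muscle list 0.535% and 6.99%.

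Of the 34 gene lists fixed in advance, 7 passed the camera test with the preset correlation, 3 higher and 4 lower in the mutant. With an estimated correlation 0 lists passed in camera (limma), 4 stood at an unadjusted p under 0.05, and the smallest adjusted p was 0.279. By fry 5 lists passed, without oxidative phosphorylation, neuropeptides and sperm (adjusted p = 0.144, 0.234 and 0.49). The lists passing with the preset correlation numbered 11 without wild-type replicate 2 and 14 without mutant replicate 2. Besides body wall muscle, the lists that were higher were those of oxidative phosphorylation and of epithelial junctions and the cytoskeleton. In oxidative phosphorylation, the mitochondrial chain that makes ATP, 9 of 41 members were higher and 0 lower (26 higher when adjusted over the list alone), with a median log2 fold change of 0.68 (adjusted p = 0.698 with an estimated correlation). The ATP synthase genes atp-1 and atp-5 and the complex III gene ucr-1 had log2 fold changes of 0.90 ± 0.19, 0.89 ± 0.18 and 0.94 ± 0.19. Without wild-type replicate 3 they were not called (adjusted p = 0.107, 0.0692 and 0.0714). Among the epithelial and cytoskeletal genes 4 of 34 were higher and 0 lower (6 higher when adjusted over the list alone), with a median of 0.14 (adjusted p = 0.298 with an estimated correlation). These were the actin genes act-1, act-3 and act-4 and the intermediate filament gene ifb-1, the last outside the naming rule and named after its value was seen. The actins had log2 fold changes of 3.49 ± 0.36, 3.69 ± 0.37 and 1.94 ± 0.22, act-4 is also on the muscle list, and the actin genes are near-identical, so that reads may be split among them. In the mutant libraries the muscle list took 6.99% ± 3.17 (SD, n = 3) of the counts outside ribosomal RNA.

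The list of excretory and coelomocyte genes was lower in the mutant, with 5 members lower and 1 higher of 19 tested (8 lower and 2 higher when adjusted over the list alone) and a median log2 fold change of -0.52. The call did not hold with an estimated correlation (adjusted p = 0.298 with an estimated correlation), without a low-count filter (adjusted p = 0.079) or with both libraries of fewest genes left out (adjusted p = 0.0878). All 5 lower members are known in coelomocytes, scavenger cells of the body cavity, although ceh-34 and rme-8 also act in other cells. They were lgc-26 (log2 fold change -0.88 ± 0.16), unc-122 (-0.83 ± 0.16), cup-4 (-0.81 ± 0.16), ceh-34 (-0.70 ± 0.15) and rme-8 (-0.64 ± 0.13), of which cup-4, ceh-34 and rme-8 lie outside the naming rule and were named after their values were seen. The member that rose was exc-5 (1.42 ± 0.28), a guanine nucleotide exchange factor of the excretory canal. The call of unc-122 ended without wild-type replicate 1 (adjusted p = 0.0674) and without wild-type replicate 3 (adjusted p = 0.0547). With both libraries of fewest genes left out, neither lgc-26 (adjusted p = 0.06) nor unc-122 (adjusted p = 0.0502) was called. The call of exc-5 ended without wild-type replicate 1, wild-type replicate 3 or mutant replicate 1 (adjusted p = 0.0515, 0.0519 and 0.0545). The list took 1.03% ± 0.0127 (SD, n = 3) of the counts outside ribosomal RNA in wild type and 0.675% ± 0.120 (SD, n = 3) in the mutant, and the groups did not overlap. The abundant genes inos-1, far-1 and mig-6, outside this list and named after their values were seen, had log2 fold changes of -0.90 ± 0.17, -0.74 ± 0.16 and -0.94 ± 0.14.

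Of the vacuolar ATPase, the proton pump of lysosomes and secretory membranes, 3 of 21 members were lower and 0 higher (7 lower when adjusted over the list alone), with a median log2 fold change of -0.42 (adjusted p = 0.433 with an estimated correlation). These were vha-1 (-0.87 ± 0.20), vha-16 (-0.61 ± 0.15) and vha-12 (-0.66 ± 0.17). Each lost its call without any of several single libraries, with adjusted p up to 0.124, 0.26 and 0.24, each without wild-type replicate 1. In the same comparison the coelomocyte genes cup-4 and rme-8 had log2 fold changes of -0.81 ± 0.16 and -0.64 ± 0.13, and the muscle list share went from 0.535% to 6.99%. Of the neuropeptide genes, 3 of 89 were lower and 0 higher (0 lower when adjusted over the list alone), with a median of -0.41 (adjusted p = 0.698 with an estimated correlation). They were ins-6 (-1.65 ± 0.38), ins-24 (-1.94 ± 0.48) and nlp-61 (-0.96 ± 0.24), none of which was called without wild-type replicate 3 (adjusted p = 0.101, 0.19 and 0.145). Without that library the list itself did not pass (adjusted p = 0.112). None of 59 sperm genes was called, also when adjusted over the list alone, and the list median was -0.46 (adjusted p = 0.867 with an estimated correlation). Its member with the smallest p, the major sperm protein gene msp-31, had a log2 fold change of -1.2 ± 0.52 (adjusted p = 0.272) and near-identical copies. Without wild-type replicate 1, wild-type replicate 2 or mutant replicate 3 the sperm list did not pass (adjusted p = 0.099, 0.291 and 0.169), nor did it with the replicate block or limma-voom (adjusted p = 0.0706 and 0.052).

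**Figure D2:**
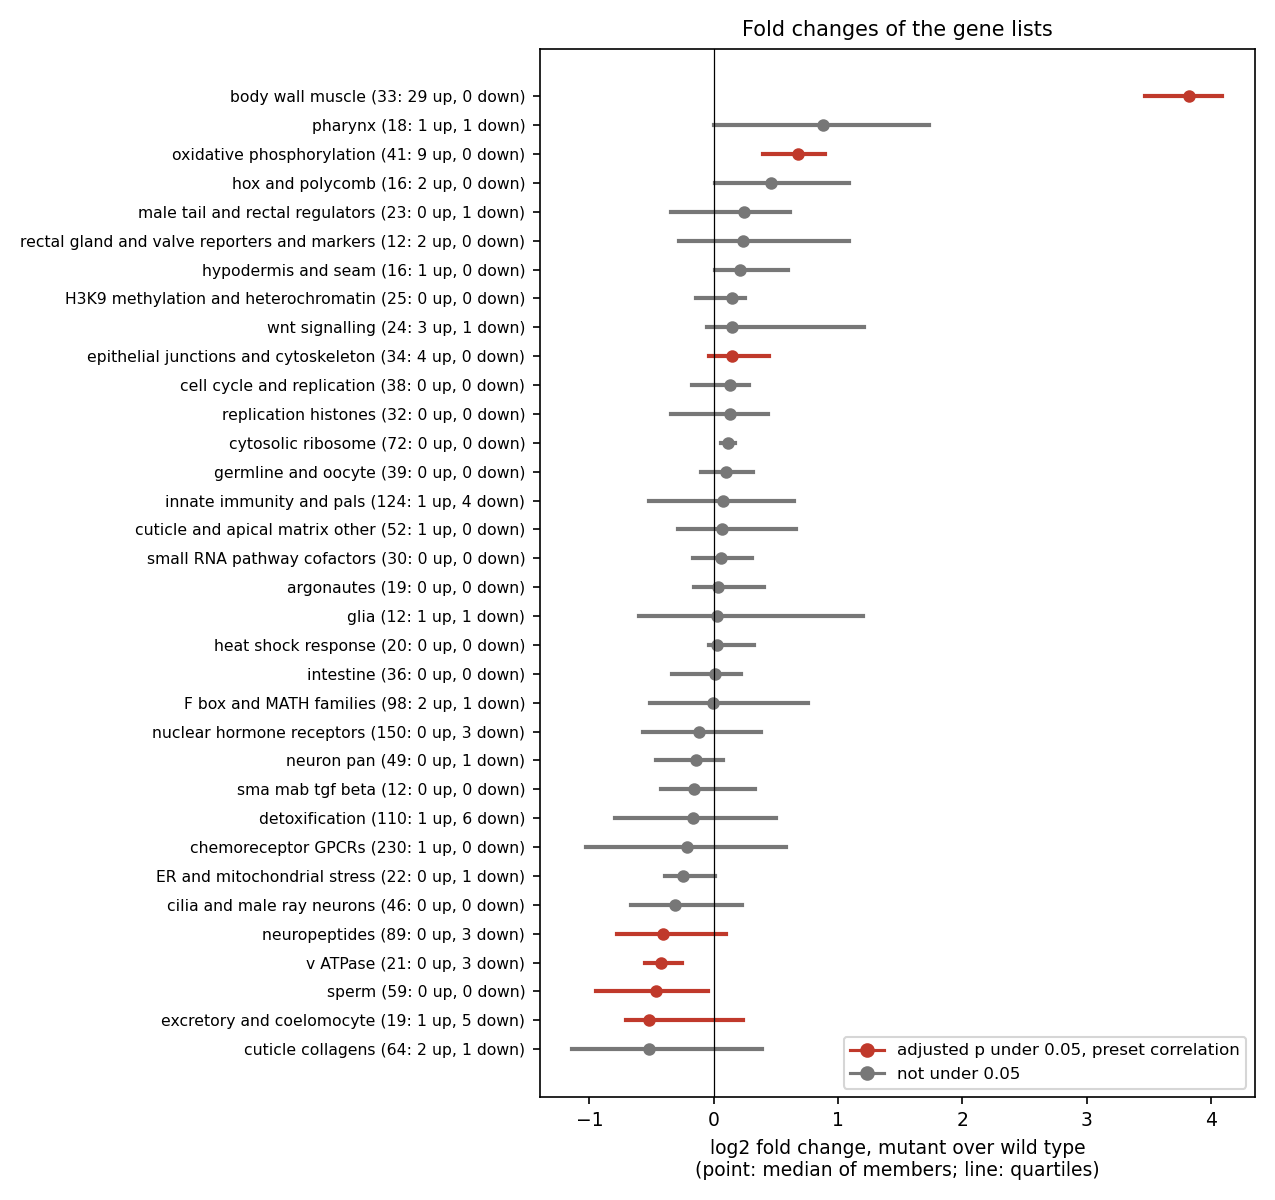
Median (point) and quartiles (line) of the log2 fold changes, mutant over wild type, of the tested members of 34 gene lists, with the tested members and the numbers called higher and lower beside each name. Red marks the 7 lists with a camera adjusted p under 0.05 at the preset correlation, and body wall muscle has a median of 3.82.

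No member was called in the lists of Argonautes (19 tested), small RNA cofactors (30) and H3K9 methylation and heterochromatin (25), nor in the heat shock response (20). Their median log2 fold changes were 0.04, 0.06, 0.14 and 0.02, with camera adjusted p of 0.938, 0.952, 0.938 and 0.938. In each of these lists 0 members passed when adjusted over the list alone. The direction of the test for small RNA cofactors was opposite in sign to the list's median. The self-test on simulated counts recovered 26 of 100 genes changed 2-fold and 89 of 100 changed 4-fold, so changes of 2-fold and below were often not detectable at this depth and spread. The simulated changes were placed only in genes above a minimum mean count, so these shares do not cover list members with few counts. The Argonaute gene sago-2, named after its value was seen, stood at 0.24 CPM in wild type. Its log2 fold change of 2.32 ± 1.17 did not pass (adjusted p = 0.366).

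In the list of male tail and rectal regulators 1 of 23 members was lower and 0 higher. It was tra-1 (WBGene00006604, chromosome III, 11170890 to 11195201), a zinc-finger regulator of somatic sex, which went from 151 ± 16.9 to 90.8 ± 13.8 CPM, a log2 fold change of -0.74 ± 0.16 (adjusted p = 0.0217). It was not called without wild-type replicate 1 or wild-type replicate 3 (adjusted p = 0.0866 and 0.0949), nor with library totals alone (adjusted p = 0.0699). Of 12 tested rectal markers and reporters, 2 were higher and 0 were lower. The higher ones were pnc-1 and pcs-1, whose promoters drove the reporter used for the sort. Together the 12 members took 0.0390% ± 0.00549 (SD, n = 3) of the counts outside ribosomal RNA in wild type and 0.0608% ± 0.00571 (SD, n = 3) in the mutant, without overlap of the groups. Most of this rise came from pnc-1 (7.18 to 22.9 CPM) and pcs-1 (13.4 to 30.3 CPM), and no other member was called. Of 16 Hox and Polycomb genes, 2 were higher and 0 lower. These were unc-62, a Meis-type homeodomain gene (3.09 ± 0.39, adjusted p = 0.000796), and ceh-13, the labial-type Hox gene (4.32 ± 0.97, adjusted p = 0.0247), which was not called without wild-type replicate 2, mutant replicate 1 or mutant replicate 3 (adjusted p = 0.0787, 0.18 and 0.0768). Of 24 Wnt genes, 3 were higher and 1 lower (4 and 1 when adjusted over the list alone). The receptor genes cam-1 (1.51 ± 0.30) and lin-18 (2.17 ± 0.49) and the Dishevelled gene dsh-1 (1.19 ± 0.25) rose, and the Frizzled gene mom-5, named after its value was seen, fell (-0.92 ± 0.23). Without wild-type replicate 2 none of cam-1, lin-18 and dsh-1 was called (adjusted p = 0.0529, 0.0705 and 0.0702). Of 12 genes of the Sma/Mab branch of TGF-beta signalling, 0 were called. Beside these changes, the muscle list share went from 0.535% to 6.99%, and the coelomocyte genes cup-4 and rme-8 had log2 fold changes of -0.81 ± 0.16 and -0.64 ± 0.13. In mutant replicates 1, 2 and 3 unc-62 stood at 54.7, 19.8 and 21.2 CPM, and the muscle list share at 10.6%, 4.97% and 5.37%. None of these lists passed camera with the preset correlation (adjusted p = 0.952, 0.37, 0.256, 0.289 and 0.938 in the order given), and the median and the test of the male tail list differed in sign.

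In the marker lists for intestine (36 tested), germline and oocytes (39) and cilia and male ray neurons (46), 0 members were called, with medians of 0.01, 0.10 and -0.31. Of 49 pan-neuronal genes 1 was lower, rgef-1 (-0.99 ± 0.16, adjusted p = 0.00346). Among 12 glia genes, egl-6 was higher (2.89 ± 0.61) and let-381 lower (-0.91 ± 0.18), and both calls ended without wild-type replicate 1 (adjusted p = 0.063 and 0.0787). The gene let-381 is also known in coelomocytes, whose genes cup-4, lgc-26 and lgc-28 had log2 fold changes of -0.81 ± 0.16, -0.88 ± 0.16 and -1.05 ± 0.19, the first and last named after their values were seen. The muscle list share beside these calls was 0.535% in wild type and 6.99% in the mutant. Among 18 pharynx genes, the T-box gene tbx-2 was higher (2.96 ± 0.43) and the lysozyme gene lys-8 lower (-1.15 ± 0.27). When adjusted over the list alone 4 pharynx genes were higher and 1 lower, and the list median was 0.88, against -0.14 for neurons, 0.03 for glia and 0.21 for epidermis. The call of lys-8 ended without wild-type replicate 1 (adjusted p = 0.169) and without 4 other single libraries. Of 16 epidermis and seam genes, 1 was higher, the cuticle collagen gene rol-6 (1.91 ± 0.28, adjusted p = 0.00207). The camera adjusted p of these lists were 0.938 for intestine, 0.894 for germline, 0.099 for cilia, 0.118 for neurons, 0.938 for glia, 0.0548 for pharynx and 0.594 for epidermis. The share of counts outside ribosomal RNA went from 0.0333% ± 0.00719 to 0.0806% ± 0.0288 (SD, n = 3) for pharynx, without overlap of the groups. For epidermis it went from 0.0256% ± 0.00376 to 0.0513% ± 0.00491 (SD, n = 3), also without overlap. Most of the epidermis rise came from rol-6 alone (16.9 to 63.1 CPM), and no other member was called, so it does not show a rise of epidermis genes in general. The pharynx list passed without a low-count filter and with limma-voom (adjusted p = 0.000188 and 0.0486), and without wild-type replicate 2, wild-type replicate 3, mutant replicate 2 or mutant replicate 3 (adjusted p = 0.0212, 0.00966, 0.0144 and 0.000816).

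Of 110 detoxification genes, 6 were lower and 1 higher. The fall was largest for pgp-9 (-1.73 ± 0.23), and the glutathione S-transferase genes gst-5 and gst-7 had log2 fold changes of -1.22 ± 0.25 and -0.93 ± 0.21. The calls of gst-5 and gst-7 ended without wild-type replicate 1, wild-type replicate 3 or mutant replicate 3, with adjusted p up to 0.07 and 0.105, and that of gst-7 also without wild-type replicate 2. The detoxification list had a camera adjusted p of 0.0548 and a fry adjusted p of 0.00504. Of 64 genes of the cuticle collagen list, rol-6 and col-99 were higher and col-122 lower (camera adjusted p = 0.0885). The list took all col genes by name, so membership does not show that col-99 is a collagen of the cuticle. The calls of col-99 (2.02 ± 0.42) and col-122 (-1.11 ± 0.26) ended without wild-type replicate 1 (adjusted p = 0.0716 and 0.132) and without other single libraries. Of 52 other cuticle and apical matrix genes, 1 was higher, lpr-2 (2.07 ± 0.46, adjusted p = 0.024), which overlaps H01G02.3 by 821 bp and was not called without mutant replicate 1 (adjusted p = 0.138) or 4 other single libraries. Of 22 genes of the ER and mitochondrial stress responses, 1 was lower, ero-1 (-0.83 ± 0.16), which was not called without wild-type replicate 1 (adjusted p = 0.0782). Of 124 immunity genes, 1 was higher, clec-149 (3.27 ± 0.71), and 4 were lower, irg-5, lys-8, pals-34 and clec-178, the last 2 named after their values were seen. Neither clec-149 nor irg-5 was called without wild-type replicate 1 (adjusted p = 0.0716 and 0.0663), and without mutant replicate 1 clec-149 had a log2 fold change of 2.22 (adjusted p = 0.261). Of 150 nuclear hormone receptors, nhr-133, nhr-88 and nhr-62 were lower, and of these none was called without wild-type replicate 1 (adjusted p = 0.147, 0.142 and 0.182). Of 98 F-box and MATH genes, btb-5 (3.86 ± 0.40) and fbxb-72 (2.45 ± 0.37) were higher and fbxa-37 (-1.50 ± 0.38) lower, the last not without wild-type replicate 1 (adjusted p = 0.114). Of 230 chemoreceptors, srx-14 was higher (2.70 ± 0.48), but not without mutant replicate 1 (adjusted p = 0.0654). In cell cycle and replication (38 tested), replication histones (32) and the cytosolic ribosome (72) 0 members were called. The camera adjusted p was 0.938 for the other matrix genes and the F-box genes, 0.0548 for stress responses, 0.952 for immunity, cell cycle and histones, 0.194 for nuclear hormone receptors and 0.18 for chemoreceptors and the ribosome. Median and test differed in sign for intestine, histones and immunity, and for F-box genes the mean and the test did. Beside the calls in these lists, the muscle list share was 0.535% in wild type and 6.99% in the mutant, and that of the excretory and coelomocyte list 1.03% and 0.675%. The share of the rectal markers and reporters was 0.0390% and 0.0608%, a rise mostly from pnc-1 and pcs-1, whose promoters drove the reporter.

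The genes that were higher in the mutant lay more often on the X chromosome than other tested genes. Of the 484 higher genes 30.2% were X-linked, against 13.7% of the other tested genes, an odds ratio of 2.73 with a 95% interval from 2.21 to 3.35 (two-sided Fisher's exact test, adjusted p = 3.01e-19). The 185 lower genes were X-linked in 17.8% against 14.3% (odds ratio 1.30, interval 0.863 to 1.92, adjusted p = 0.290). On the autosomes 54.7% of the higher genes lay on the arms, the outer parts when a chromosome is cut into 3 equal lengths, against 55.7% of other genes (odds ratio 0.960, interval 0.768 to 1.2, adjusted p = 0.738), and 50.7% of the lower genes did against 55.8% (odds ratio 0.814, interval 0.583 to 1.14, adjusted p = 0.290). The odds ratio for lower genes on the arms was 0.648 without a low-count filter (adjusted p = 0.00132) and 0.683 with limma-voom (adjusted p = 0.0243). Genes are not independent, so these p-values describe the gene sets and not replicate animals. The muscle list, which took 6.99% of the counts outside ribosomal RNA in the mutant and 0.535% in wild type, had 27.3% of its 33 tested members on X.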

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

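Leaving out ribosomal RNA genes, both libraries with the fewest genes or the muscle list genes was chosen after seeing the data. Genes changed numbered 1048 without a low-count filter (727 genes higher in the mutant and 321 genes lower in the mutant) and 1039 with DESeq2 (339 lower), where more genes were tested. Genes lower in the mutant numbered 89 with library totals alone, 65 with an absolute log2 fold change of 1 or more and 56 with both libraries of fewest genes left out; the cause was not tested beyond the smaller number of libraries in the last. With muscle list genes left out, 457 genes were higher and 165 lower. Leaving out each library in turn gave 416 to 697 genes changed and 39 to 151 lower, with the lowest values without wild-type replicate 1. Higher members of the muscle list numbered 21 to 31 in the alternatives, where fewer members were tested at the lowest value, and the list median log2 fold change lay between 3.31 and 4.14. Gene lists passing numbered 0 with an estimated correlation, 0 higher and 0 lower. Lists higher in the mutant numbered 5 without a low-count filter and 5 with limma-voom. Without single libraries 7 to 14 lists passed, 3 to 5 higher and 3 to 9 lower, with the highest values without mutant replicate 2; the cause was not tested. The odds ratio of lower genes on autosome arms was 0.648 without a low-count filter and 0.683 with limma-voom, both past the threshold (adjusted p from 0.00132 to 1 over the alternatives), and the cause was not tested. The odds ratio of higher genes on X lay between 2.21 and 3.12 and passed in all of them. Of 68 named genes, 24 had the same call under every alternative, among them csr-1, him-8 and msp-31, which were not called in any. Without at least 1 single library, 37 lost their call. A change of sign was counted only where the main run or the alternative called the gene, and 0 genes reversed so. The uncalled him-8 did change sign, with log2 fold changes from -0.37 to 0.11.

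The replicate numbers do not pair the libraries. The correlations of deviations of same-numbered libraries were 0.0370, -0.0201 and -0.0680, and not every library correlated best with its own number. With the replicate block, 560 genes changed, 429 higher and 131 lower, and 6 lists passed, without sperm. At these depths, 2-fold changes were recovered for 26 of 100 simulated genes above a minimum mean count, so small changes can be missed. Larger ones can be missed in genes with few counts, which the simulated changes did not cover.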

Other observations

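The tests of muscle RNA, of a lower share of the main cells, of the larger total of mutant replicate 1, of genes outside the muscle list and of coelomocyte genes were chosen after the results were seen, and the bounds for genes outside the list were reset after their ratios had been seen. For both tests on the X chromosome the bounds were set before their values were seen, but the bootstrap interval and the demand that Fisher's exact tests pass were added afterwards. The genes in the next paragraph were also chosen after their values were seen.

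Genes known in coelomocytes, the scavenger cells of the body cavity, were among the most abundant outside ribosomal RNA in these sorted cells. By mean level in wild type, cubn-1 ranked 9 with 1827 ± 132 CPM, cup-4 ranked 16 with 982 ± 64.8 CPM, lgc-28 ranked 17 and lgc-26 ranked 18. In the mutant they ranked 20, 32, 55 and 45. Other abundant genes fell too, since dig-1, inos-1, far-1 and mig-6, ranked 1, 2, 3 and 7, had log2 fold changes of -1.13 ± 0.15, -0.90 ± 0.17, -0.74 ± 0.16 and -0.94 ± 0.14 (adjusted p = 0.00111, 0.0109, 0.0235 and 0.00179). Which cells these transcripts come from was not tested, so they cannot show whether the fall was particular to coelomocyte transcripts. The gene aman-1, ranked 6, had a log2 fold change of -0.53 ± 0.14 and did not pass (adjusted p = 0.0624). The 12 tested members of the list of rectal markers and reporters lay lower, between 0.41 ± 0.409 CPM (pax-3) and 33.3 ± 3.40 CPM (ajm-1) in wild type. Among them lin-48 stood at 0.437 ± 0.344, egl-26 at 2.43 ± 0.521, vab-3 at 7.62 ± 3.19 and dlg-1 at 27 ± 6.62 CPM, and ajm-1 and dlg-1 are also found in other epithelia. Of the type IV collagen genes of basement membranes, let-2 went from 187 ± 26.6 to 1234 ± 562 CPM and emb-9 from 39.9 ± 10.0 to 484 ± 252 CPM (log2 fold changes 2.72 ± 0.28 and 3.60 ± 0.34). The pharyngeal myosin genes myo-2 and myo-1 had log2 fold changes of 1.93 ± 0.53 and 1.74 ± 0.52 and did not pass (adjusted p = 0.0610 and 0.0855).

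More muscle cells or muscle RNA among the sorted mutant cells is a candidate explanation for the higher muscle genes, to which the 87.9% of list members called higher, as the pattern itself, lends no support. It needs other muscle genes to be higher too, and 28 tested ones outside the list, taken from general knowledge, had a median log2 fold change of 2.41 (quartiles 1.56 to 2.79), with 20 called higher (71.4% against 3.65% of other genes outside the list, Fisher's exact test, p = 6.55e-23). Genes are not independent, so this p-value describes the gene set and not replicate animals. Not all of the 28 rose. Named after their values were seen, egl-19, lim-8, stn-1 and unc-63 had log2 fold changes of -0.04 ± 0.23, -0.25 ± 0.23, -0.10 ± 0.25 and 0.17 ± 0.28. None of the 28 was called lower. Their upper quartile of 2.79 lay below the muscle list's lower quartile of 3.47. The tables argue against a lower share of the main cells that raises every other type alike, because the lower quartile of the muscle list lay 3.19 above the upper quartile of 151 members of the intestine, germline, neuron, glia and epidermis lists (the pharynx list, not among them, had an upper quartile of 1.73, also under the 3.47 of the muscle lower quartile), and against the larger total of mutant replicate 1, because the muscle median was 3.31 without it. Over 390 of the 455 genes called higher outside the list, those with a mean of at least 5 CPM in either group, the median log2 ratio of mutant replicate 1 to the mean of replicates 2 and 3 (0.5 CPM added) was 0.89 (quartiles 0.59 to 1.14) against 1.19 (1.07 to 1.27) for the 30 muscle list members and -0.04 (-0.32 to 0.24) for the 4788 genes not called above the same limit, with 128 genes at or above that list's lower quartile and 262 below, and 1.196 (0.90 to 1.41) against 1.33 (1.24 to 1.42) after the wild-type mean was subtracted, so muscle RNA may account for part of them and how many stays open. Muscle genes switched on within the sorted cells by the loss of csr-1a would give much the same values and stay open as untested, as does a sort gate that passed more muscle in the mutant.

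All 8 coelomocyte members of the excretory and coelomocyte list had lower levels in the mutant. Over all genes tested, 5 of them passed the test, and 0 of the 11 other members were called lower. When adjusted over the list alone, vha-8 (-0.44 ± 0.15), among these other members, was lower too, and the coelomocyte member cup-5 (-0.67 ± 0.32) did not pass. Both were named after their values were seen. Dilution by muscle RNA alone would lower alike the genes of other tissues whose transcripts muscle does not hold. The upper quartile of the coelomocyte members lay below the lower quartile of 124 intestine, germline and neuron members, with a difference of -0.39. Whether muscle holds transcripts of these 124 members was not tested, so the difference cannot decide whether dilution was the whole cause. Lists left out of this comparison fell too, with medians of -0.46 for sperm and -0.41 for neuropeptides, while the pharynx list had a positive median. A smaller share of coelomocytes in the mutant sort, and a change within these cells that follows from the genotype, may each account for the fall and were not tested, nor was a fall shared with the most abundant genes named above.

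The genes higher in the mutant were X-linked in 30.2%. A rise of the whole X chromosome would need a median log2 difference of at least 0.3 between X-linked and autosomal genes. The difference was 0.0896, with a 95% bootstrap interval over genes (treated as independent) from 0.0319 to 0.140, which argues against a rise of that size but spans the bound of 0.1 set for its absence, so a smaller rise stays open. Muscle genes could account for part of it. Of the list members 27.3% were X-linked, against 14.3% of all tested genes. Against the 13.6% of 11295 genes outside the list that were not called, Fisher's exact test gave p = 0.0365, with genes again treated as independent. Outside the list, 137 of the 455 genes called higher were X-linked (30.1%), close to the 30.2% of all higher genes. The list members by themselves therefore do not account for the X-linked share. Among 390 genes called higher outside the list and above 5 CPM, however, 128 with a muscle-like ratio in mutant replicate 1 were X-linked in 32.8%. The other 262 were X-linked in 29.01% (Fisher's exact test, p = 0.482). Whether muscle genes account for the X-linked share cannot be told apart from other sources by these counts, and an effect of csr-1a on X-linked genes was not tested.

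With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes changed, 1 of the 10 splits, the real grouping with 669, gave as many, and the highest of the others was 0. For lists passing, 5 of the 10 splits gave at least the 7 of the real grouping, and the highest of the others was 12.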
